A study of Mus musculus with 4 samples.

How the data were processed

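Single-cell RNA was measured with the 10x Genomics 3′ v2 chemistry in 4 libraries of mouse kidney cells: E15.5, E17.5, P0, and embryonic kidneys grown as a transplant for 12 days. Each group is 1 library. Per the submitters' processing notes the reads were aligned to GRCm38 and counted with Cell Ranger 3.1.0. The deposited values are UMI counts per gene and barcode, already limited by the authors to barcodes called as cells, and per the file headers the count matrices were made with version 3.0.2 for E15.5 and P0 and 3.1.0 for E17.5 and the transplant. How that software treated strand and reads shared by near-identical genes is not given in those sources, so values of Hspa1a, Ccl21a, Sprr2f, the Klk1 and class I families and the antisense gene Atcayos are uncertain in how reads were split. A joined matrix of 3 of the libraries was not used here.

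The libraries held 4158 (E15.5), 5551 (E17.5), 10810 (P0) and 7670 (transplant) barcodes with 92387054, 42430540, 99068204 and 57855356 UMIs. Cells with at least 500 genes and at most 20% of UMIs from mitochondrial genes were kept. This left out 465, 696, 1980 and 787 barcodes for too few genes and 128, 292, 738 and 265 for mitochondrial UMIs. Scrublet in scanpy 1.11.5 was run per library, and the highest scores were removed at 0.8% per 1000 cells, which took 102, 167, 524 and 350 cells. The 21695 cells used were 3463 at E15.5, 4396 at E17.5, 7568 at P0 and 6268 in the transplant. Their median UMIs were 22585, 7197.5, 9885.5 and 6276.5, and their median genes 4697, 2590, 2944.5 and 2495.5.

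Counts were scaled to 10000 per cell and log-transformed. From 20672 genes, 2000 variable genes were chosen within libraries, leaving out the genes of the fixed lists (class markers stayed in), mitochondrial, ribosomal protein and globin genes, Xist and Y-linked genes. The 4 libraries were clustered together with 40 principal components, 15 neighbours and Leiden resolution 1.5 (python-igraph 0.11.9, scikit-learn 1.9.0), giving 40 clusters. A cluster took the name of 1 of 21 fixed marker classes, written as "X-like", when at least 3 markers of the class were at least 2 times their level in the other cells. Of these classes 14 names were carried by clusters, and no cluster carried the urothelium, granulocyte, mast, neural or glial, adipocyte, mesothelium or epididymis name. Details of the naming were set after the clusters had been seen: the mean log2 fold of the markers had to be above 0, and genes of the lineage lists counted against a name when they led a cluster, meaning its 10 leading genes at 100 CPM or more with 10 CPM added. Clusters of low UMI content also stayed unnamed. The 6 unnamed clusters held 2351 cells, 10.8% of all: 7.51% of the E15.5 cells, 10.7% at E17.5, 9.61% at P0 and 14.3% of the transplant.

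Shares of cells are given with exact Clopper-Pearson 95% intervals. For gene levels the UMIs of a gene were summed over the cells of a class in a library and divided by all UMIs of that class and library, scaled as CPM. Ratios of CPM carry exact conditional binomial 95% intervals. All intervals are counting error only. With 1 library per group the variation between animals, litters and dissociations is not measured, no test was made and no gene is called changed. A gene with 0 counts in a library has its ratio given as a bound, from a floor of 3 counts in that library. Ratios whose smaller count was 1 to 3 UMIs are marked as such.

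Before the data were examined, the marker classes, 27 gene lists (16 for lineages, 11 general), the comparisons, the filters and 11 alternative settings were fixed. For each list in a class of at least 10 cells in both libraries, the median log2 ratio was taken over the genes with at least 20 UMIs, with 0.5 counts added. Its interval came from 500 Poisson draws. Its percentile among 10000 random lists, matched in size and in expression over 20 bins, describes these libraries and is not a test. A further list per class was chosen from these data: genes at P0 at least 2 times E15.5 by the lower interval bound and at least 2 times the other named cells of P0. It was chosen on a random part of the cells and measured in the rest, for classes of at least 20 cells (random seed 1).

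The genes named per class follow a fixed rule, applied to classes of at least 50 cells in both libraries. It takes the 2 genes with the highest and the 2 with the lowest ratio by the interval bound nearest 1. A gene needs at least 50 UMIs over both libraries, and at least 2 times the CPM of the other named cells in the library where it is higher. The class markers and the technical genes above were left out. From each fixed list, the genes quoted are from the 2 highest and the 2 lowest by the log2 ratio itself, among genes with at least 50 UMIs. The interval bound was not used for these, so extreme ratios on few counts in 1 library were not screened out. Some genes that these rules name are not reported here. Genes of the clustering also lead clusters, and 7 of the 32 genes the rule named for P0 against E15.5 and 5 of the 32 for the transplant against P0 are among the leading genes of a cluster.

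The alternative settings were: at most 10% mitochondrial UMIs, at least 1000 genes, no doublets removed, resolution 0.8, each library clustered on its own, median-of-ratios scaling, removal of a free RNA profile at 10%, at least 100 UMIs per gene, list genes kept in the clustering, the 2 parts of the cells exchanged, and means over cells. A further alternative, chosen after seeing the data, split the collecting system and distal clusters again at resolution 1.

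The ratio step was tested on simulated data with 200 changed genes, 50 per fold size. For the proximal tubule-like comparison of transplant and P0 (11859 genes) the interval lay on the right side of 1 for 82.0%, 98.0%, 100% and 100% of genes changed 1.5, 2, 4 and 8 times, and held the true ratio for 95.8% of unchanged genes. For the podocyte-like comparison of P0 and E15.5 (10117 genes) the shares were 56.0%, 84.0%, 98.0% and 100%, with 96.0% of unchanged genes covered. These figures hold for counting error alone. Gene positions are from GENCODE M21 on GRCm38, where 529 of 529 looked-up gene IDs matched. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used.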

Results

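The data are single-cell counts from kidneys at 3 ages, E15.5, E17.5 and P0, and from kidneys taken at E12.5 and grown for 12 days in the epididymal fat of host mice. There is 1 library of each. The series is about stages of maturation in the developing kidney. The comparisons ask which gene groups of each cell class differ between the youngest and the oldest kidney in situ, where E17.5 lies, and how the transplanted kidney compares with the newborn one. Per the labels, E15.5 and P0 are ICR mice, E17.5 is C57BL/6 and the transplant C57BL/6N, so strain goes with E17.5 and with the transplant and cannot be set apart from them. The transplant also differs from P0 in total time of growth, in host and in site, and these cannot be set apart either. The labels conflict on the host, giving NOD immunodeficient mice in one place and C57BL/6N in another. The libraries held 92387054 (E15.5), 42430540 (E17.5), 99068204 (P0) and 57855356 (transplant) UMIs. The cells used had median UMIs of 22585, 7197.5, 9885.5 and 6276.5, so E15.5 cells were read deepest.

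The cell classes show a nephrogenic kidney at the 3 ages and a kidney without progenitors in the transplant. Nephron progenitor-like cells were 21.1% [19.8, 22.5] of cells at E15.5, 14.5% [13.5, 15.6] at E17.5 and 12.9% [12.2, 13.7] at P0, and 0 of 6268 transplant cells (upper bound 0.0588%). Early nephron-like cells were 14.5%, 14.0% and 12.3%, and 0.431% [0.284, 0.626] in the transplant. The differentiated nephron took larger shares. Podocyte-like cells were 3.47% [2.88, 4.13], 6.48%, 8.60% [7.98, 9.26] and 10.4% [9.66, 11.2] in the order E15.5, E17.5, P0 and transplant, and loop of Henle-like cells 1.07% [0.753, 1.47], 5.14%, 8.11% [7.51, 8.75] and 10.2% [9.43, 10.9]. Proximal tubule-like cells were 3.15% [2.59, 3.78], 13.0%, 8.60% and 16.4% [15.5, 17.3]. With each library clustered on its own, their share in the transplant was above that of P0 by 1.01 points, against 7.78 points here. Distal tubule-like cells were 0.837%, 1.55%, 0.674% (51 cells) and 7.07% (443 cells), and intercalated-like cells 0.404%, 0.773%, 0.846% and 3.94% [3.47, 4.45]. The low distal share of P0 depends on which clusters carry the name. When the distal and collecting clusters were split again, 1 distal-like subcluster alone held 1, 48, 175 and 1 cells in the same order.

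Collecting duct-like cells were 3.78% [3.17, 4.47], 3.94% and 8.60% of the in situ libraries, and no transplant cell fell in a cluster of that name. Without doublet removal they were 6.03%, 9.80%, 9.13% and 1.47%, so the order of E17.5 and P0 depends on the setting. The removed cells do not account for it. At E17.5 the filter took 167 cells, while without it the class went from 173 to 447 cells. The unnamed cells of E17.5 went from 469 to 203, so the naming of clusters moved as well. Clusters of the transplant carried collecting duct genes under another name: the distal cluster, with 443 transplant cells, was led by Slc12a3, S100g and Tmem52b and also by Scnn1b, Hsd11b2 and Fxyd4. Splitting these clusters again, a step chosen after seeing the data, placed 84 transplant cells among 224, 435 and 708 collecting duct-like cells at E15.5, E17.5 and P0. Outside the epithelium, stroma-like cells were 30.6% [29.1, 32.2] at E15.5 and 13.9%, 11.4% and 11.9% after, endothelium-like cells 6.99%, 10.9%, 12.4% and 11.7%, and mural-like cells 1.82%, 3.69%, 4.76% and 9.46% [8.75, 10.2]. Erythroid-like cells were 3.29%, 0.660%, 1.08% and 0.383%. Macrophage-like cells were 48, 34, 1 and 120, and lymphoid-like cells 1, 0, 8 and 119. Without doublet removal P0 held 56 macrophage-like cells, so the low number of the class at P0 goes with that filter, and the lymphoid-like cells were 0, 0, 7 and 42. Unnamed clusters held 7.51%, 10.7%, 9.61% and 14.3% of cells, with 470 cells of 1 cluster of low UMI content found in the transplant only. Depth, dissociation and strain can each set these shares.

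**Figure D1:**
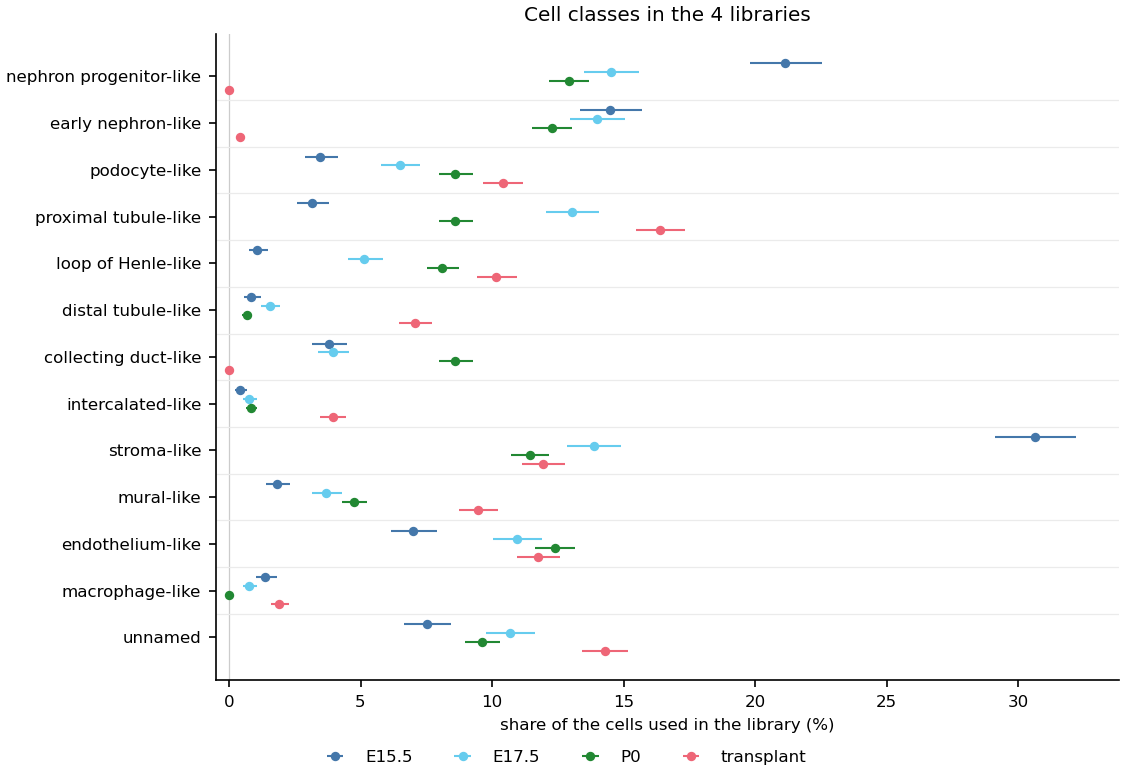
Share of the cells used in each library (percent, x axis) for each class (y axis), with points for the 4 libraries and lines for exact 95% counting intervals. Nephron progenitor-like cells go from 21.1% at E15.5 to 12.9% at P0 and 0 in the transplant.

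Some classes were the same clusters at every age and others were not. Podocyte-like cells at E15.5 lay almost wholly in 1 cluster (98.3%), which held 58.5% of the P0 podocyte-like cells, while a second held 56.5% of those at E17.5 and 40.9% at P0, and 31.0% in the transplant. Another, with 414 transplant cells beside 4 at E17.5 and 4 at P0, held 63.5% of the transplant ones. Among proximal tubule-like cells 1 cluster held 86.2% of the class at E15.5, 37.3% at E17.5 and 70.0% at P0, a second 62.1% at E17.5, and another 96.3% in the transplant. Clusters with few cells of other libraries also held 91.7% of the transplant's stroma-like, 46.2% of its mural-like and 50.2% of its loop of Henle-like cells, and 32.2% and 36.4% of its endothelium-like cells in 2 clusters. A further 41.0% of its loop of Henle-like cells lay in a cluster with 261 transplant cells of 470. At P0, nephron progenitor-like cells lay mostly (68.9%) in a cluster that held 10.5% of the E15.5 ones.

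P0 against E15.5 asks what the oldest and youngest kidneys in situ, of the same strain label, show in each lineage. The P0 library held 8181 tdTomato UMIs and the E15.5 library 0, so the animals may differ in genotype under the same label. Such a difference cannot be set apart from age. The genes of mature function were mostly higher at P0. Programs of the progenitor, the ureteric tip and cell division were lower. In proximal tubule-like cells enzymes and transporters parted. The CPM values have a median log2 ratio over all genes between -0.22 (intercalated-like) and -0.02 (podocyte-like), and scaling this away turned the sign of the proliferation list of early nephron-like cells, from -0.03 to 0.04.

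In podocyte-like cells the maturation list had a median log2 ratio of 0.43 [0.36, 0.54], with 18 of 21 genes higher, above 99.88% of matched random lists. Other settings gave 0.21 (libraries clustered alone) to 0.70 (mean over cells). Sema3g, a semaphorin of podocytes, was at 22.5 CPM at E15.5 and 178 CPM at P0 (7.92-fold [5.97, 10.7]), and Rhpn1 was 4.34-fold higher. Cdkn1c, the p57 cell cycle inhibitor, was 1.81-fold lower. The adult basement membrane list had a median of 0.69 [0.43, 0.91] with 8 of 9 genes higher, and the embryonic list one of -0.14 [-0.33, -0.03]. Col4a3 (ENSMUSG00000079465, chromosome 1, 82586921 to 82722059, plus strand), a chain of the mature glomerular collagen network, was at 18.2 and 195 CPM (10.8-fold [7.89, 15.04]), and its partner Col4a4 was 7.84-fold higher. Pax2 and Fn1, genes of the podocyte's precursors, were 2.47-fold and 2.60-fold lower. By the fixed rule, Lpl (lipoprotein lipase) was 32.6-fold higher [17.6, 68.4] and the class I gene H2-Q6 118-fold [20.9, 4677] on 1 UMI at E15.5, while Etd and Tmem8 were 12.3-fold [6.81, 23.9] and 8.33-fold [6.15, 11.5] lower.

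In proximal tubule-like cells the enzyme list was higher at P0, with a median of 0.62 [0.55, 0.72] and 20 of 23 genes, while the transport list was lower, at -0.16 [-0.32, -0.01], with 11 of 27 genes higher. The transport value turned to 0.03 with at least 1000 genes per cell and 0.38 with libraries clustered alone, where the enzyme value was 1.33. Kap, the androgen-regulated kidney protein (ENSMUSG00000032758, chromosome 6, 133849851 to 133853762, minus strand), had 0 counts at E15.5 and 123 CPM at P0, at least 126.5-fold higher. Cyp27b1, which activates vitamin D, was 42.2-fold higher [11.6, 349.9] on 2 UMIs at E15.5. The lactate transporter Slc5a12 was 6.87-fold higher [4.04, 12.7] and the urate transporter Slc22a12 3.13-fold lower [2.75, 3.56]. Serpina6, corticosteroid-binding globulin, was at 0.325 CPM (1 UMI) and 90.0 CPM (277-fold [49.6, 10950.0]). The metallothionein Mt2 was 20.1-fold lower [19.1, 21.2], from 2932 to 146 CPM, and Cited4 10.6-fold lower [8.64, 13.2]. Kap, Serpina6 and Mt2 also lead clusters.

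The loop of Henle-like list was higher by 1.16 [0.87, 1.47] in 19 of 20 genes. It was 0.37 with at most 10% mitochondrial UMIs and 1.86 with list genes kept in the clustering. Ptger3, a prostaglandin E2 receptor, was 10.7-fold higher [5.13, 26.7]. The distal list had a median of 0.56 [0.40, 0.87] on 29 and 51 cells and took the opposite sign in 4 of 11 alternatives, down to -1.34 after the second split. S100g, the calcium-binding calbindin D9k, was 10.9-fold higher there. In collecting duct-like cells the principal cell list was higher by 1.82 [1.48, 2.23] in 15 of 15 genes. This size depends on which cells the class holds, since settings that change the cells or the clusters gave 0.54 to 0.68, and resolution 0.8 gave -0.32. The second split gave 0.55 [0.42, 0.69]. The vasopressin-regulated water channel Aqp2 (ENSMUSG00000023013, chromosome 15, 99579055 to 99584547, plus strand) was at 14.6 CPM at E15.5 and 1411 CPM at P0 (96.7-fold [75.4, 126]), and Aqp3 was 24.4-fold higher. After the second split, which places more Aqp2-bearing E15.5 cells in the class, Aqp2 was at 86.6 and 1630 CPM (18.8-fold) and Aqp3 5.24-fold higher. The ureteric tip list had a median of -0.82 [-0.95, -0.74], and was -0.33 after the second split and -0.08 at resolution 0.8. Its transcription factors Emx2 and Sox8 were 7.31-fold and 8.95-fold lower. By the rule, Gdf15, a cytokine of stressed cells, was 169-fold higher [116, 256], at 6.36 and 1072 CPM, and Sprr1a, a cornified envelope gene, 205-fold [87.6, 631]. Both lead clusters. The calcium sensor gene Vsnl1 was 48.2-fold lower [20.1, 151] and Spata7 11.03-fold lower [9.38, 13.0].

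Nephron progenitor-like cells at P0, taken as a class, carried less of the progenitor program and more of the differentiation program. The class was made of other clusters at each age. A cluster led by Cited1, Crym and Six2 held 58.7% of it at E15.5 and 2.25% at P0. Another, with Wnt4 among its leading genes, held 10.5% and 68.9%. A change in this mixture cannot be told apart from a change within cells. The regulator list had a median of -0.39 [-0.47, -0.35], with 3 of 16 genes higher, and the differentiation list one of 1.02 [0.87, 1.12], with 12 of 15 genes higher. The latter ranged from 0.61 to 1.91 over the alternatives. Fgf20, which keeps progenitors alive, was 11.1-fold lower [6.89, 18.96] and Bmp7 3.07-fold lower. Npy was 8.01-fold and Bmp2 5.0-fold higher. Chac1 and Trib3, targets of the ATF4 stress pathway, were 92.0-fold [46.3, 214] and 100.2-fold [38.7, 371] higher, at 38.5 and 20.99 CPM. Rspo3, an amplifier of Wnt signals, was at 104 CPM at E15.5 and 7.48 CPM at P0 (13.9-fold lower [11.3, 17.2]) and leads a cluster, and Fam19a4 was at least 15.6-fold lower. In early nephron-like cells the smooth muscle gene Lmod1 was 41.7-fold higher [19.98, 105] and Acta1 97.4-fold [17.0, 3888] on 1 UMI. The nuclear receptor Nr1h5 was at least 53.9-fold lower and Olfr655 22.4-fold lower [11.6, 49.6].

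Outside the epithelium, the endothelial list had the largest median of these lineages, 1.67 [1.56, 1.74], in 17 of 20 genes. Cd300lg was 20.9-fold higher [11.2, 44.1] and Plat, tissue plasminogen activator, 15.7-fold [13.4, 18.5]. Sox18 was 2.72-fold lower. The mural list was higher by 0.77 [0.57, 0.84] in 14 of 18 genes, and 0.34 with at least 1000 genes per cell. Rgs4 and Higd1b, pericyte genes, were 34.4-fold [17.3, 80.3] and 18.8-fold [7.87, 58.7] higher. The stromal matrix list was higher by 0.82 [0.73, 0.91] in 17 of 20 genes, with Col15a1 3.90-fold and Col6a1 3.81-fold higher. The nephrogenic zone list was near 0, at 0.22 [-0.29, 0.28], and below 0 in 2 alternatives, while its genes Ntn1, a guidance cue, and Aldh1a2, which makes retinoic acid, were 4.88-fold and 3.25-fold lower. By the rule, Ttc21a was 274-fold [92.7, 1338] (3 UMIs at E15.5) and Atcayos 127-fold [34.1, 1069] (2 UMIs) higher in stroma-like cells, with Crabp1, a retinoic acid-binding protein, 18.6-fold [13.5, 26.4] and Pianp 13.4-fold [7.60, 26.1] lower. In mural-like cells Hspa1a was 527-fold [242, 1436] and Cebpb 61.2-fold [41.7, 93.9] higher, and Shisa3 was 3.58-fold lower [2.88, 4.46]. In endothelium-like cells the glutamate receptor gene Gria2 was 32.0-fold lower [10.5, 159] (3 UMIs at P0) and Mmrn1 10.4-fold lower [6.78, 16.7].

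**Figure D2:**
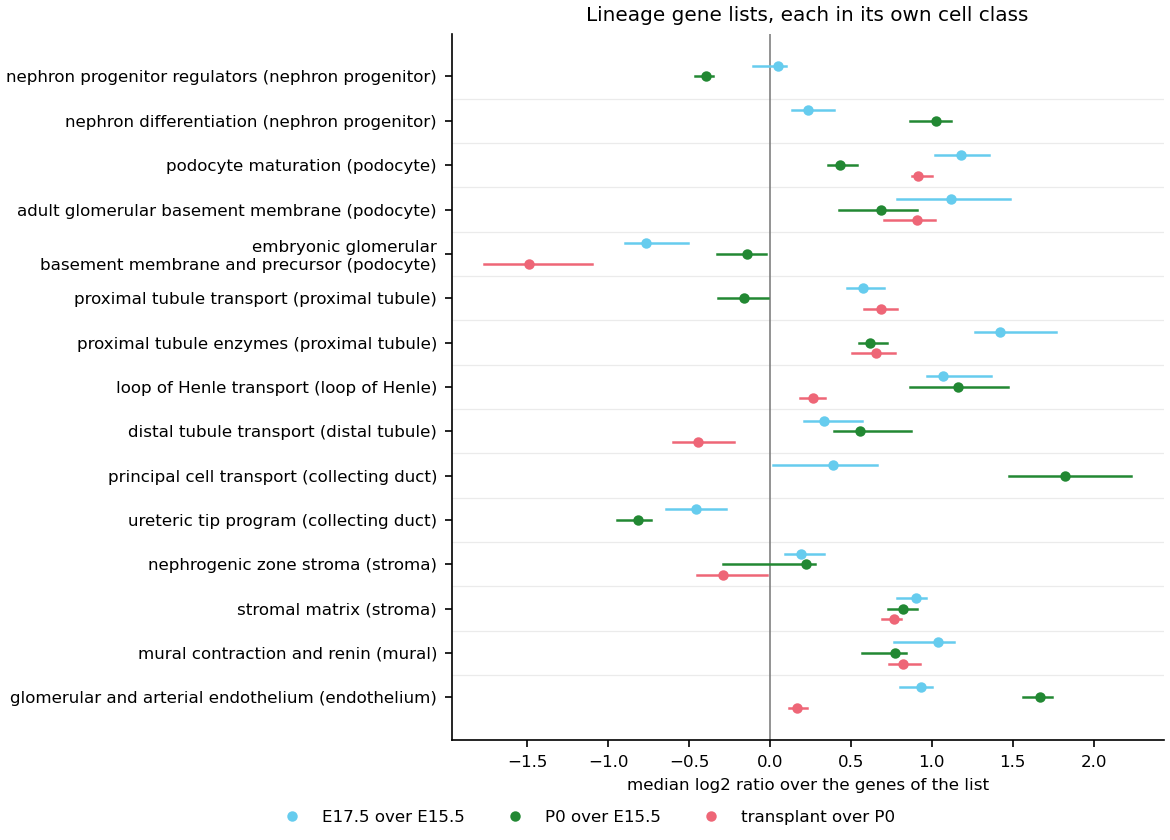
Median log2 ratio (x axis) over the genes of each lineage list (y axis, with its class), with points for the comparisons and lines for 95% counting intervals. The loop list is 1.16 for P0 over E15.5 and the podocyte maturation list 0.91 for the transplant over P0, where scaling turns the loop list to -0.08 and the endothelial list to -0.14, and that of progenitor regulators for E17.5 over E15.5 to -0.01.

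Most general lists went the same way in every class compared. Proliferation was lower at P0 in 11 of 11 classes, from -1.80 in distal tubule-like to -0.03 in early nephron-like cells (above 0 in 4 alternatives, up to 0.04 when scaled). Top2a and Cenpf were 6.79-fold [5.31, 8.71] and 6.38-fold [4.81, 8.49] lower in loop of Henle-like cells. Fetal growth and imprinted genes were lower in all 11, from -1.26 in intercalated-like to -0.28 in endothelium-like cells. In stroma-like cells Hmga2 was 3.18-fold and Igf2bp1 2.59-fold lower. Oxidative phosphorylation genes were higher in 3 classes and lower in 8, from -0.44 (endothelium-like) to 0.49 (loop of Henle-like), with intercalated-like cells (0.08) down to -0.15 and distal tubule-like cells (-0.19) up to 0.23 in other settings. Fatty acid oxidation genes ran from -0.19 (distal tubule-like, 0.34 with libraries clustered alone) to 0.57 (loop of Henle-like), higher in 8, and the small values of nephron progenitor-like, podocyte-like, proximal tubule-like and intercalated-like cells also turned in some settings, to between -0.06 and 0.01. Glycolysis was higher in all 11 classes, from 0.58 (distal tubule-like) upwards, and so was hypoxia, from 0.46 (intercalated-like) to 2.08 (endothelium-like). In proximal tubule-like cells the phosphofructokinase gene Pfkl was 4.30-fold higher [3.56, 5.23] and Adm, the hypoxia target adrenomedullin, 22.8-fold [7.70, 111] on 3 UMIs at E15.5. These lists move with the dissociation stress list, which was higher at P0 in all 11 classes, from 0.98 (intercalated-like) to 3.25 (endothelium-like).

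The other lists of response were also higher at P0 in every class compared, beside the same stress difference. Glucocorticoid response ran from 0.65 (intercalated-like) to 2.94 (mural-like), with the metallothionein Mt1 33.9-fold higher [24.9, 47.4] in mural-like cells and the kinase Sgk1 32.8-fold [21.1, 53.8] in collecting duct-like cells, where the same list's Fkbp5 and Mt2 were 2.55-fold and 3.53-fold lower. Tubular injury ran from 0.63 (intercalated-like) to 2.09 (loop of Henle-like) and was 1.91 [1.16, 2.06] in proximal tubule-like cells. In distal tubule-like cells it was 1.67, and -0.17 as a mean over cells. Class I antigen presentation ran from 0.74 (nephron progenitor-like) to 2.76 (endothelium-like). Hspa1a, the inducible heat shock protein (ENSMUSG00000091971, chromosome 17, 34969190 to 34972156, minus strand), was at 1.11 and 1584 CPM in endothelium-like cells (1423-fold [722, 3296]).

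The interferon list was higher at P0 in 9 of 9 classes, from 0.58 in collecting duct-like to 3.92 [3.63, 4.26] in endothelium-like cells, with 2.87 in mural-like, 2.33 in stroma-like and 1.74 in podocyte-like cells. Free RNA removal turned it below 0 in nephron progenitor-like (0.81 to -0.86) and early nephron-like cells (0.89 to -0.61). In endothelium-like cells Isg15, the interferon-induced ubiquitin-like protein (ENSMUSG00000035692, chromosome 4, 156199424 to 156200818, minus strand), was at 1.81 CPM at E15.5 and 241 CPM at P0 (133-fold [77.7, 250.4]). Ifit1 and Gbp2 had 0 counts at E15.5 and were at least 57.5-fold and 24.5-fold higher. Rsad2, the antiviral viperin, was at 135 and 364 CPM. Summed over the list, endothelium-like cells held 551 CPM at E15.5, 4758 at E17.5, 4457 at P0 and 3699 in the transplant.

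**Figure D3:**
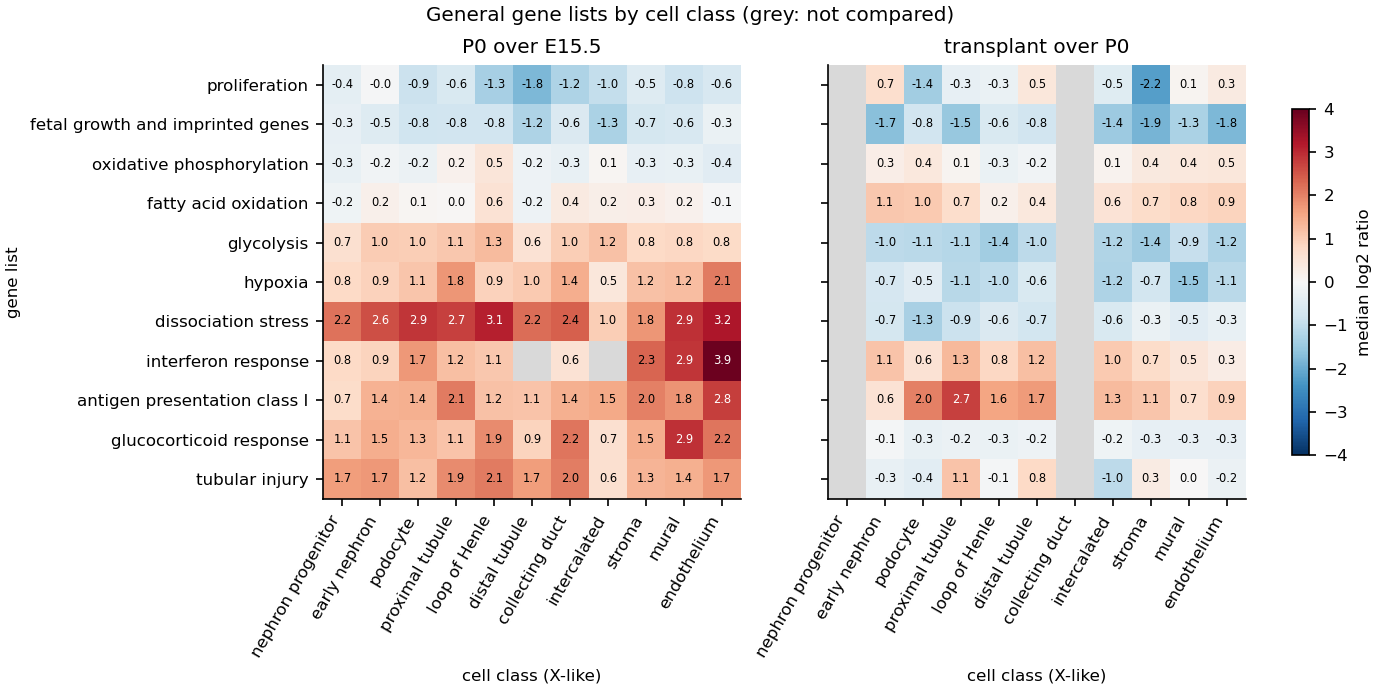
Median log2 ratio (colour and printed value) of each general list (y axis) in each cell class (x axis), P0 over E15.5 and transplant over P0, with grey where a class was not compared. Glycolysis is above 0 in 11 of 11 classes on the left and below 0 in 9 of 9 on the right, and scaling turns -0.03 of proliferation to 0.04 (early nephron-like) on the left, and on the right it turns 0.21 of fatty acid oxidation to -0.14 (loop of Henle-like), 0.29 of interferon to -0.02 (endothelium-like), 0.12 of proliferation to -0.15 and 0.02 of injury to -0.25 (both mural-like), and oxidative phosphorylation from 0.26 to -0.02 (early nephron-like), 0.12 to -0.12 (proximal tubule-like) and 0.13 to -0.21 (intercalated-like).

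E17.5 against E15.5 sets an age in between, in another strain, beside the youngest kidney. Most lineage lists were higher at E17.5, and in podocyte-like and proximal tubule-like cells they stood above P0 as well. In progenitor-like cells the regulator list stood near 0, with genes on either side. The median of all genes lies between -0.05 (intercalated-like) and 0.23 (macrophage-like), and scaling turns the progenitor regulator list from 0.05 to -0.01, in endothelium-like cells proliferation from 0.06 to -0.08 and fetal growth from 0.10 to -0.05, class I from -0.04 to 0.02 (intercalated-like) and 0.08 to -0.01 (early nephron-like), and oxidative phosphorylation from 0.09 to -0.01 (early nephron-like) and 0.14 to -0.09 (macrophage-like).

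Podocyte maturation was 1.18 [1.02, 1.35] with 21 of 21 genes higher, and 0.84 [0.64, 1.0] above P0. Sema3g was 17.7-fold [13.3, 23.9] and Rhpn1 9.37-fold higher than at E15.5. The adult basement membrane list was 1.12 [0.79, 1.48], with Col4a3 16.6-fold higher [12.1, 23.4], and the embryonic list -0.77 [-0.89, -0.51]. Proximal tubule enzymes were 1.42 [1.26, 1.77] with 23 of 23 genes higher, and transport 0.58 [0.47, 0.70]. The transport value was 1.30 with libraries clustered alone. Above P0 these lists stood at 0.88 [0.76, 1.16] and 0.78 [0.69, 0.88]. Kap was at 282 CPM, at least 289.8-fold higher than at E15.5, Cyp27b1 195.8-fold on 2 UMIs [54.0, 1620.1], and Slc5a12 11.1-fold [6.54, 20.6]. The loop list was 1.07 [0.97, 1.37] in 17 of 17 genes, with Ptger3 7.35-fold higher, and the distal list 0.33 [0.21, 0.57], with S100g 8.65-fold higher. Principal cell transport was 0.39 [0.02, 0.66], with Aqp2 8.36-fold higher [6.31, 11.2], and the tip list -0.46 [-0.64, -0.27]. After the second split these lists were 0.76 [0.69, 1.01] and -0.87. Over the alternatives the embryonic list ran from -0.94 to -0.33, the enzymes up to 2.32, the loop list from 0.68 to 1.77, the distal list from 0.11 to 1.43, principal cell transport from 0.12 to 0.88 and the tip list from -0.92 to -0.16.

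In nephron progenitor-like cells the regulator list was 0.05 [-0.10, 0.10] (-0.01 when scaled) and the differentiation list 0.23 [0.14, 0.40], with Wnt4 and Pax8, genes of the first epithelial step, 2.02-fold and 2.06-fold higher and Fgf20 5.69-fold lower. The differentiation list ran from -0.07 to 0.55 over the alternatives. The endothelial list was 0.94 [0.81, 1.0], with Cd300lg 18.3-fold and Ly6a 6.85-fold higher, the mural list 1.04 [0.77, 1.14], with Art3 6.49-fold higher (0.53 with at least 1000 genes per cell), the stromal matrix list 0.90 [0.78, 0.96], with Col15a1 3.56-fold higher, and the nephrogenic zone list 0.19 [0.09, 0.33]. Macrophage-like cells (34 and 48) had 1.21 [1.10, 1.69] for the resident macrophage list in 11 of 13 genes, with the cytokine Il1b 10.1-fold [7.28, 14.2] and Ms4a7 4.71-fold higher. Over the pooled libraries, the cluster of this class also had the granulocyte marker S100a8 among its leading genes. A change in the mix of its cells cannot be told apart from a change within macrophages.

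Of the general lists at E17.5, glycolysis (0.23 to 0.92), hypoxia (0.67 to 1.38), glucocorticoid response (0.54 to 1.56) and tubular injury (0.11 to 1.41) were above 0 in 12 of 12 classes, as was dissociation stress (0.88 to 2.67). Of these, glucocorticoid response in distal tubule-like cells turned to -0.56 with at least 100 UMIs per gene, and injury in nephron progenitor-like cells to -0.47 with free RNA removed. The interferon list was above 0 in 10 of 10, from 0.45 in collecting duct-like to 3.68 in endothelium-like cells, with 3.44 in mural-like, 2.94 in macrophage-like and 2.90 in stroma-like cells. With free RNA removed it was -0.06 in nephron progenitor-like cells and -0.39 in early nephron-like cells. Class I genes ran from -0.04 (intercalated-like, 0.02 when scaled) to 1.86 (endothelium-like), above 0 in 11 classes and with the whole interval above 0 in 6, and early nephron-like cells turn to -0.01 when scaled. Other settings gave -0.39 and -0.15 in nephron progenitor-like, -0.22 in early nephron-like, -0.58 in distal tubule-like and up to 0.34 in intercalated-like cells. Proliferation ran from -1.55 (intercalated-like) to 0.34 (early nephron-like), lower in 7 of 12, where other settings took collecting duct-like cells (0.10) to -0.25, macrophage-like cells (0.30) to -0.20 and mural-like cells (-0.05) to 0.29. The stroma-like (-0.01) and endothelium-like (0.06) values turned as well, to 0.07 and -0.10, and fetal growth ran from -1.52 (macrophage-like) to 0.10 (endothelium-like, -0.05 when scaled), lower in 11, of which stroma-like and mural-like cells reached 0.01. Oxidative phosphorylation ran from -0.12 (podocyte-like) to 0.54 (proximal tubule-like), and fatty acid oxidation from -0.14 (distal tubule-like) to 0.57 (loop of Henle-like). In distal tubule-like cells these lists reached 0.55 and 0.68 with libraries clustered alone, and in intercalated-like cells they turned from 0.14 to -0.03 and from 0.17 to -0.09.

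The transplant against P0 asks which gene groups of the grafted kidney differ from those of the newborn one. Podocyte and proximal tubule functions, matrix and mural genes were higher in the transplant. Glycolysis, hypoxia and fetal growth genes were lower in every class, as were stress genes except in early nephron-like cells under 1 alternative. Genes of antigen presentation were higher in every class, most of all in proximal tubule-like cells. The median of all genes lies between 0.15 (podocyte-like) and 0.35 (loop of Henle-like), and scaling it away turns the loop list from 0.27 to -0.08 and the endothelial list from 0.16 to -0.14.

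In podocyte-like cells the maturation list was higher in the transplant by 0.91 [0.88, 1.0] in 19 of 21 genes, where matched random lists stood at 0.19. As a mean over cells it was 0.55. Ddn (dendrin) and Enpep (aminopeptidase A) were 3.73-fold and 3.44-fold higher. The adult basement membrane list was 0.91 [0.70, 1.02] in 7 of 9 genes, and the embryonic list -1.49 [-1.77, -1.10], with 1 of 9 higher, which ran from -2.68 (free RNA removed) to -0.72 (mean over cells). Col4a3 was at 195 CPM at P0 and 800.5 CPM in the transplant (4.10-fold [3.79, 4.44]), Col4a5 was 3.09-fold higher, and Pax2 was 6.20-fold lower [3.45, 12.1]. By the rule, Efemp1, a fibulin, was 27.0-fold higher [14.8, 54.7] and Rhbdl3 49.1-fold [13.2, 412] on 2 UMIs at P0, and Lrrc17 and C1ql1 were 49.1-fold [16.5, 240.4] and 53.9-fold [14.6, 450.2] lower on 3 and 2 UMIs in the transplant.

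In proximal tubule-like cells transport was higher by 0.69 [0.58, 0.78] in 23 of 27 genes and enzymes by 0.65 [0.51, 0.77] in 18 of 24. Scaled, they were 0.45 and 0.41. The glucose transporter Slc5a2 (ENSMUSG00000030781, chromosome 7, 128265657 to 128272430, plus strand) was at 11.6 and 120 CPM (10.4-fold [8.65, 12.51]), and the amino acid transporter Slc6a19 was 13.0-fold higher [8.70, 20.3]. Miox, an enzyme of inositol breakdown, was 8.94-fold higher [8.11, 9.88], and Cyp27b1 7.52-fold lower. By the rule, the lipid desaturase Scd2 was 60.5-fold lower [49.9, 74.1], from 445 to 7.36 CPM, and Serpina6 61.1-fold lower [39.8, 99.2].

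Loop of Henle-like transport was 0.27 [0.18, 0.34] in 12 of 20 genes (-0.08 when scaled) and ran to 0.65 with libraries clustered alone. Kcnj16, a potassium channel, was 2.24-fold higher and Ptger3 2.32-fold lower. By the rule, Fxyd3 was 177-fold [31.4, 7014] on 1 UMI and Gabrp 58.7-fold [19.8, 287] on 3 UMIs higher, and Fam71a 100.2-fold [27.3, 834] and Pvalb 118-fold [20.7, 4726] lower on 2 and 1 UMIs in the transplant. The distal list was -0.44 [-0.60, -0.23] on 51 P0 cells and took the other sign in 8 of 11 alternatives, up to 2.51 with at most 10% mitochondrial UMIs. Calb1 and the exchanger Slc8a1, of calcium transport, were 9.77-fold [8.36, 11.4] and 11.8-fold lower, and the phosphate transporter Slc20a1 12.3-fold lower [6.82, 21.9]. Klk1, tissue kallikrein, was 38.1-fold higher [17.5, 104], at 743 CPM, and Sprr2f 100.3-fold [34.3, 487] on 3 UMIs, though its log2 ratio was -0.08 when no doublets were removed. In intercalated-like cells Klk1 was 373-fold higher [128, 1811] on 3 UMIs and Hsd11b2, which inactivates corticosteroids, 40.9-fold [24.8, 73.2], while Maff and Igfbp1 were 99.2-fold [65.1, 158] and 60.6-fold [24.3, 195] lower. Klk1, Hsd11b2, Sprr2f and Serpina6 lead clusters. In the second split, an intercalated-like subcluster led by Klk1 held 190 transplant and 0 P0 cells, another without it 33 and 56, and a distal-like one with Klk1 216 and 1. In the collecting duct-like cells of the second split, principal cell transport was 2.16 [2.07, 2.30] in 16 of 17 genes, with Hsd11b2 at 73.4 and 834 CPM (11.4-fold [10.3, 12.53]) and Aqp2 at 1630 and 3033 CPM, and the tip list was -1.37, with the tip receptor Ret at 84.0 and 1.40 CPM (2 UMIs). The class is not made of the same cells in both libraries: 78 of the 84 transplant cells lay in a subcluster with no P0 cell, led by Sprr2f, Fxyd4 and Plet1, while 118 and 202 of the 708 P0 cells lay in 2 subclusters whose leading genes include Ret.

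In stroma-like cells the matrix list was 0.77 [0.69, 0.81] in 19 of 20 genes, with the elastic fibre gene Fbln5 3.77-fold higher, and the nephrogenic zone list -0.29 [-0.45, -0.02], with Tcf21 3.42-fold higher and Aldh1a2 7.69-fold lower. Lrrtm1 and Rprm were 81.2-fold [40.9, 189] and 50.3-fold [29.7, 92.6] higher, and Dkk1, a Wnt antagonist, and Ttc21a at least 85.9-fold and 60.3-fold lower. The mural list was 0.82 [0.74, 0.92] in 13 of 18 genes, with the angiotensin receptor Agtr1a 3.34-fold higher. Ccl6 was 76.1-fold [13.4, 3035] on 1 UMI and Angptl4 9.49-fold [6.91, 13.4] higher, Dlk1 37.1-fold [16.7, 103] and the cytokine Il6 25.8-fold [12.7, 60.8] lower. The endothelial list was 0.16 [0.11, 0.23] (-0.14 when scaled, -0.15 with libraries clustered alone), with Sox18 and Cd300lg 7.36-fold and 7.27-fold higher and Aqp1 2.96-fold lower. The lymphatic chemokine Ccl21a was 1352-fold [242, 53473] on 1 UMI at P0, at 133 CPM in the transplant, where it leads a cluster, and Ablim3 81.4-fold [21.9, 682] on 2 UMIs. Tiparp was 42.2-fold lower [32.9, 55.0] and the imprinted noncoding RNA H19 (ENSMUSG00000000031, chromosome 7, 142575529 to 142578143, minus strand) 34.0-fold lower [30.3, 38.4], at 1569 and 46.1 CPM.

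Of the general lists, fetal growth was lower in the transplant in 9 of 9 classes, from -1.86 (stroma-like) to -0.62 (loop of Henle-like). The early nephron-like value on 27 transplant cells was -1.66, and -0.82 with 0 counts at their bound. In proximal tubule-like cells Igf2 was 29.5-fold [23.6, 37.2] and H19 25.8-fold lower. Glycolysis was lower in 9 of 9, from -1.44 (stroma-like) to -0.93 (mural-like), with the hexokinase Hk2 14.7-fold [7.93, 30.2] and the glucose transporter Slc2a1 5.58-fold lower in proximal tubule-like cells. Hypoxia was lower in 9 of 9, up to -0.45 in podocyte-like cells and -1.12 in proximal tubule-like cells, where Ankrd37 was 22.0-fold [15.03, 33.5] and Egln3 49.1-fold [16.4, 242] lower, the latter on 3 UMIs. The dissociation stress list moves with these, lower in 9 of 9 from -1.29 (podocyte-like) to -0.25 (stroma-like), though early nephron-like cells turn from -0.71 to 0.30 with list genes kept in the clustering, with Hspa1a 47.5-fold lower in podocyte-like cells. Glucocorticoid response ran from -0.33 to -0.08, with the whole interval below 0 in 4 of 9 classes, and turned to 0.28 (podocyte-like) and 0.12 (distal tubule-like) as means over cells and to 0.40 (early nephron-like) with list genes kept in the clustering. Fatty acid oxidation was higher in 9 of 9, from 0.21 (loop of Henle-like, -0.14 when scaled) to 1.09 (early nephron-like), with 0.70 [0.64, 0.74] in proximal tubule-like cells, where the peroxisomal enzyme Ehhadh was 11.1-fold higher [8.86, 14.2]. Oxidative phosphorylation ran from -0.28 (loop of Henle-like) to 0.46 (endothelium-like), above 0 in 7, and scaling turns it to -0.12 in proximal tubule-like, -0.02 in early nephron-like and -0.21 in intercalated-like cells. Distal tubule-like cells (-0.15) took values from 0.13 to 1.37 in other settings, and loop of Henle-like cells 0.01 with at most 10% mitochondrial UMIs. Proliferation was lower in 5 of 9, with -2.21 [-2.41, -2.0] in stroma-like cells, where Top2a was 8.75-fold [7.17, 10.8] and Ube2c 12.2-fold lower, and -1.40 in podocyte-like cells, against 0.35 in endothelium-like and 0.68 in early nephron-like cells, and scaling turns mural-like cells from 0.12 to -0.15. With free RNA removed proximal tubule-like cells turn from -0.33 to 0.40, loop of Henle-like from -0.27 to 0.15 and intercalated-like from -0.49 to 0.15, and distal tubule-like cells (0.45) lay between -2.18 and -1.03 in 6 alternatives.

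Antigen presentation by class I was higher in 9 of 9 classes, from 0.58 (early nephron-like) to 2.73 [2.54, 2.88] in proximal tubule-like cells, where 9 of 9 genes were higher, the immunoproteasome gene Psmb8 18.6-fold [11.8, 31.2] and B2m 3.52-fold. Interferon response was higher in 9 of 9, from 0.29 (endothelium-like, -0.02 when scaled) to 1.30 [1.19, 1.69] in proximal tubule-like cells, though above the central 95% of matched random lists in 3 only. The summed CPM of the list was lower than at P0 in endothelium-like (3699 against 4457) and podocyte-like cells (216 against 245). By the rule, the top genes of proximal tubule-like cells were Ubd, an inducible ubiquitin-like protein (ENSMUSG00000035186, chromosome 17, 37193892 to 37196095, plus strand), at 0.0913 CPM (1 UMI) and 103 CPM (1125-fold [202, 44473]), and Cd74, the class II invariant chain (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652, plus strand), at 18.5 and 1357 CPM (73.2-fold [63.7, 84.4]). Tubular injury ran from -1.04 in intercalated-like cells to 1.13 [1.04, 1.22] in proximal tubule-like cells. Scaling turned mural-like cells from 0.02 to -0.25 (-1.31 with free RNA removed), and other settings turned distal tubule-like cells from 0.79 to as low as -1.45 and the small negative values of podocyte-like, endothelium-like and loop of Henle-like cells to between 0.01 and 0.32. Both ends turned sign, the former under most alternatives and the latter with libraries clustered alone (-0.15). The matrix protein gene Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050, plus strand) was at 145 and 4132 CPM (28.4-fold [27.0, 29.9]) in proximal tubule-like cells, and Krt18 2.43-fold lower.

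The last comparison takes, within each class, the genes that were at least 2 times higher at P0 than at E15.5 in a part of the cells, and follows them in the rest. The transplant medians of the podocyte, proximal tubule and stroma genes lay near those of P0, with genes going both ways (17, 12 and 42 at least 2 times higher, 24, 15 and 43 lower). Those of the loop stood lower. The E17.5 medians over E15.5 lay below those of P0 in all classes but the proximal tubule, though set directly against P0 the podocyte genes of E17.5 were level, at -0.01 [-0.17, 0.11]. Since the genes were picked for being high at P0, any other library tends to lie below P0 by that choice alone. Of 67 podocyte genes the medians over E15.5 were 2.57 at P0, 2.14 at E17.5 and 2.07 in the transplant, and the transplant over P0 -0.23 [-0.34, -0.06], with 33 of 67 higher. For 58 proximal tubule genes they were 1.93, 2.15 and 1.76, and -0.11 [-0.17, 0.05]. The last value took the opposite sign in 4 alternatives for each, within -0.40 to 0.27 and -0.34 to 0.39. For 89 loop of Henle genes they were 2.57, 1.84 and 1.80, and -0.73 [-0.82, -0.62], which was 0.06 with list genes kept in the clustering. They were, for 189 stroma genes 1.89, 1.63 and 2.09, and 0.05 [-0.01, 0.16] (-0.19 when scaled), for 184 mural genes 2.23, 1.52 and 1.79, and -0.35 [-0.47, -0.27], and for 384 endothelium genes 2.28, 1.56 and 1.97, and -0.35 [-0.41, -0.30]. The 26 distal genes had 1.67, 0.91 and 1.49, and -0.29 [-0.41, -0.13], which ran from -2.58 to 0.28 over the alternatives. The 26 early nephron genes had 1.79, 1.35 and 1.27, and -0.79, where 12 had a 0 count and the transplant medians with these at their bound were 0. Nephron progenitor genes (72) were 2.19 at P0 and 1.21 at E17.5, and collecting duct genes (234) 2.72 and 1.13. The genes were chosen on these libraries, so the split of the cells removes counting noise only. It does not remove the advantage that the choice gives to P0, and a median below P0 is not read as less maturity.

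**Figure D4:**
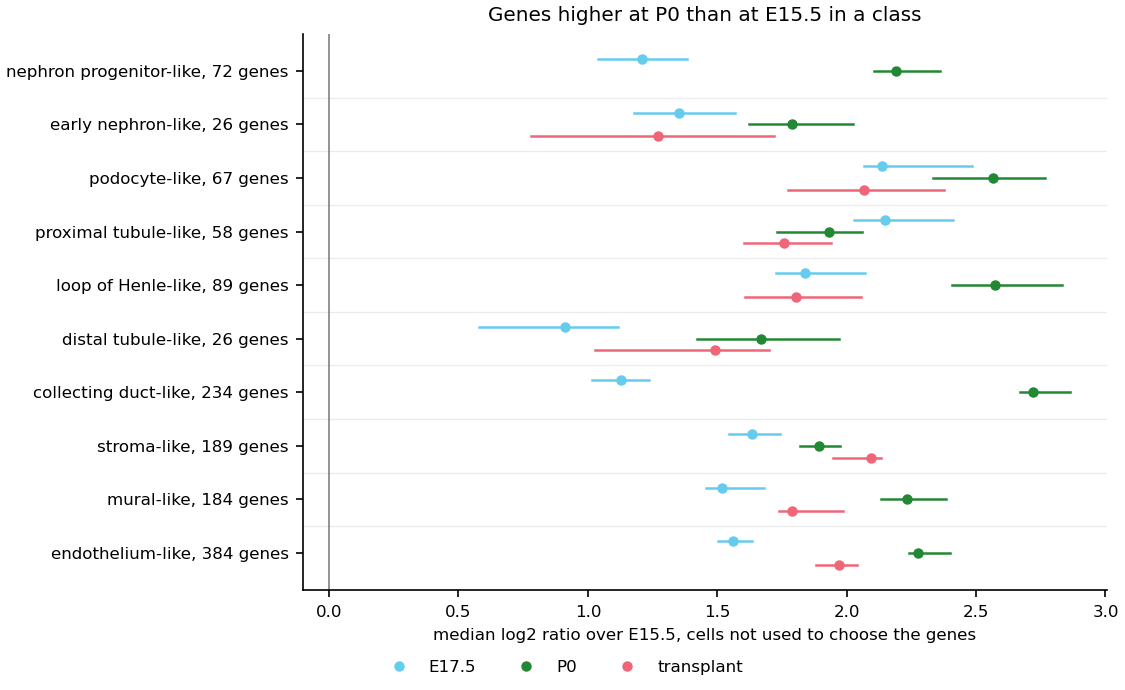
Median log2 ratio over E15.5 (x axis) of the genes higher at P0 in each class (y axis, with the number of genes), in cells not used to choose them, with points for E17.5, P0 and transplant and lines for 95% counting intervals. Podocyte genes are at 2.57 for P0 and 2.07 for the transplant, and scaling turns the transplant over P0 median of stroma genes from 0.05 to -0.19. The choice of genes favours P0.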

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

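Of the tests below, those of strain, of free RNA for the interferon and tdTomato patterns, and of a mouse gene read as tdTomato were chosen only after the result was seen. The tests of young cells, leukocytes, handling stress and the share of mural-like cells with tdTomato were set before.

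Podocyte maturation, proximal tubule transport and proximal tubule enzyme genes were higher in the transplant than at P0, by medians of 0.91, 0.69 and 0.65. If strain were the cause, a C57BL/6 kidney in situ should also stand above the ICR kidney of P0. The E17.5 library did, by 0.78 at the lowest of the 3 lists, although it is younger. That outcome cannot single out strain. The mature podocyte-like cluster used below held 56.5% of the class at E17.5 and 40.9% at P0, and the proximal tubule-like one 62.1% and 29.8%. The matrices of E17.5 and the transplant were also made with version 3.1.0, that of P0 with 3.0.2. Against P0 cells of a mature cluster alone the podocyte list was 0.070 [-0.06, 0.17], the transport list -0.0089 [-0.08, 0.35] and the enzyme list 0.14 [0.09, 0.22]. Only the P0 side was narrowed, to clusters whose leading genes include 4 of the podocyte, 3 of the enzyme and 0 of the transport list, so a lower value is built in for the former 2, the transport interval reaches past its limit of 0.34, and a larger share of young cells at P0 cannot be told apart from a difference within cells. Strain stays open as a candidate explanation, and the age and host of the transplant were not tested apart from it.

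The interferon list of endothelium-like cells was higher at P0 than at E15.5 by 3.92. Free RNA is argued against because nephron progenitor-like cells, in the same suspension, held 1.23% of the excess of endothelium-like cells (48.0 against 3906 CPM). For leukocytes among the cells, their genes stood at 0.0591% of the level needed (8.07 against 13668 CPM). That level was set by the 56 macrophage-like P0 cells found without doublet removal. Their interferon sum (4010 CPM) lies under that of endothelium-like cells (4457 CPM). A share of 97.4% would be needed, which the class could hardly reach, so no conclusion is drawn from that test. The leukocyte genes of endothelium-like cells were at 16.7 CPM at E15.5 and 8.07 at P0, so no rise of leukocyte RNA was seen. For handling stress, the 312 P0 cells with the least stress RNA gave 3.72 [3.44, 4.12]. Their stress list stayed at 2.04 above E15.5, so they are no unstressed group and the test cannot decide. Handling stress stays open. Age, a difference in genotype, and differences between 2 single libraries or litters stay open too and were not tested.

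UMIs of tdTomato, a reporter gene outside the comparisons, were found in the P0 library at 82.6 CPM (8181 UMIs in 3497 of 10810 barcodes) against 0 in the other 3, which made it stand out as above the limit that 0 counts allow. Free RNA alone is argued against because classes differed by 25.8 times, from 22.4 CPM in early nephron-like to 578 [548, 610] in mural-like cells. A mouse gene read as tdTomato is argued against because the other libraries allow at most 0.0856% of the P0 level. Of the P0 mural-like cells 50% [44.7, 55.3] had a tdTomato UMI, where 102 genes of like level had a median of 86.9% and 2 lay below 50%, so whether these cells are of 2 kinds cannot be told apart from uneven RNA. No biological explanation was tested, as the labels name no reporter.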

How the results depend on the processing

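The split again of the collecting system was chosen after seeing the data, the other settings before. Of 4498 list medians under the alternatives 4328 had the sign reported and 170 the opposite, of 1788 whose reported size was at least 1 log2 1777 had the same sign, and 3448 lay within the counting interval. Of 512 ratios of named genes 511 had the same sign. The rule had picked these genes for extreme ratios in the same libraries, so a kept sign is largely built in. The lists of genes higher at P0 were not computed as means over cells, and named genes were not recomputed under scaling, at least 100 UMIs, means over cells or the exchanged parts. The cause of the moves was not tested.

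With at most 10% mitochondrial UMIs the podocyte share of the transplant exceeded P0 by 0.763 points, podocyte maturation was 0.34 (P0 over E15.5) and 1.06 (transplant over P0), loop transport 0.37 and 0.53, principal cell transport 0.63, injury in intercalated-like cells (transplant over P0, opposite) 1.51 and the podocyte genes higher at P0 (transplant over P0) 0.16. With at least 1000 genes the proximal tubule share of P0 exceeded E15.5 by 6.43 points and that of the transplant P0 by 5.19, and the podocyte share 0.638. Podocyte maturation was 0.25 (P0 over E15.5), proximal tubule transport and enzymes 0.031 and 0.97 (P0 over E15.5) and 1.02 and 1.04 (transplant over P0), transport 0.89 (E17.5 over E15.5), principal cell transport 0.61, intercalated injury 0.38 (opposite) and proximal tubule genes higher at P0 0.26. With no doublets removed podocyte maturation was 0.34, principal cell transport 0.68, podocyte genes higher at P0 0.18, and Sprr2f in distal tubule-like cells (transplant over P0) -0.081, opposite. At resolution 0.8 principal cell transport was -0.32 and intercalated injury 0.27, both opposite.

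With each library clustered on its own the proximal tubule share differences were 3.35 (P0 and E15.5) and 1.01 points (transplant and P0), podocyte maturation 0.21 and 1.01, proximal tubule transport and enzymes 0.38 and 1.33 (P0 over E15.5) and 0.98 and 0.99 (transplant over P0), transport 1.30 (E17.5 over E15.5), loop transport 0.65 (transplant over P0) and principal cell transport 0.55. Injury was -0.15 in proximal tubule-like and 0.071 in intercalated-like cells (both opposite), and the podocyte and proximal tubule genes higher at P0 were -0.35 and 0.39. Under median-of-ratios scaling, transplant over P0, podocyte maturation was 0.76, proximal tubule transport and enzymes 0.45 and 0.41, loop transport -0.079, and the podocyte, proximal tubule and stroma genes higher at P0 -0.40, -0.34 and -0.19. With free RNA removed at 10% the interferon list of nephron progenitor-like cells (E17.5 over E15.5) was -0.058, opposite, and podocyte genes higher at P0 -0.40.

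With at least 100 UMIs intercalated injury was 0.82, opposite. With list genes kept in the clustering the proximal tubule share of P0 exceeded E15.5 by 3.78 points, transport and enzymes were 0.57 and 0.47 (transplant over P0), transport 0.46 (E17.5 over E15.5), loop transport 1.86 (P0 over E15.5) and 0.56 (transplant over P0), principal cell transport 0.54, intercalated injury 0.28 (opposite) and proximal tubule genes higher at P0 -0.27. With the parts exchanged, podocyte and proximal tubule genes higher at P0 were 0.27 and -0.22. As means over cells podocyte maturation was 0.70 (P0 over E15.5), 0.55 (transplant over P0) and 0.94 (E17.5 over E15.5), transport 0.44 (E17.5 over E15.5), loop transport -0.011 (transplant over P0) and injury in distal tubule-like cells (P0 over E15.5) -0.17, opposite. After the split again principal cell transport was 0.55, intercalated injury 0.49 (opposite) and podocyte genes higher at P0 0.037.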

Other observations

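Everything in this part was looked at after the data had been seen. The transplant held 2 kinds of lymphoid-like cells. A cluster with 80 transplant cells carried T cell receptor and CD3 genes (Trbc2 1716 CPM, Cd3g 1432, Cd3e 651) with the cytotoxic genes Nkg7 at 2544 and Cd8a at 386 CPM, little Cd4 (23.3 CPM) and no Cd79a. Another, with 39 transplant cells, carried the B cell genes Ighm at 3567, Cd79a at 2817 and Ms4a1 at 979.8 CPM and no Cd3e. The labels name both an immunodeficient and an ordinary host strain, and these libraries do not tell graft from host cells.

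Class II genes in proximal tubule-like cells went with the class I genes of the report. From P0 to the transplant H2-Aa was at 4.02 and 256 CPM, H2-Ab1 at 41.6 and 543, H2-Eb1 at 11.7 and 259, and their activator Ciita at 1.37 and 9.53, beside Cd74 at 18.5 and 1357. In transplant podocyte-like, stroma-like and endothelium-like cells Cd74 was at 39.6, 38.5 and 27.1 CPM, and in macrophage-like cells at 26419. Ubd was at 103 CPM in proximal tubule-like and 2.95 CPM in macrophage-like cells of the transplant. In E15.5 and E17.5 macrophage-like cells Cd74 was at 42.8 and 88.9 CPM, so class II expression of that kind was seen in the transplant and not in those 2 ages.

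The unnamed clusters are of several kinds, and some matched a marker class before the rules on leading genes and UMI content took the name away. The 1 led by Upk3a and Krt19, genes of the urothelium, with Aqp2 and Fxyd4 of the collecting duct, held 111, 276, 67 and 9 cells in the order E15.5, E17.5, P0 and transplant, and another of 16, 51, 240 and 317 cells was led by Ms4a2, Cpe and Tagln. A cluster of low UMI content was led by Abhd2 and Spp1 and held 470 transplant cells. Of the 736 endothelium-like cells of the transplant, 237 lay in a cluster led by Ccl21a, Aplnr and Ly6c1, 268 in one led by Ehd3 and Cd300lg, genes of glomerular endothelium, and 211 in one led by Stmn2, Gja4 and Sox17 that all 4 libraries share.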
